A study of Mus musculus with 18 samples.

How the data were processed

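Gene expression was measured by RNA sequencing in 18 libraries of mouse bone marrow-derived macrophages: 3 WT and 3 Ldha KO animals, each untreated, with IFN-gamma for 24 h and with IL-4 for 24 h. Per the labels, marrow cells were grown for 7 days in medium with 15% serum and 30 ng/mL macrophage colony-stimulating factor, RNA was taken with Trizol, and libraries were made with a directional kit after poly(A) selection and read on a NextSeq500. Genotype, treatment and animal code came from the labels, and the replicates of a group are separate animals by these codes.

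Per the submitters' processing notes, reads were aligned with STAR 2.5 to GRCm38, counted per gene with HTSeq 0.6 and tested with DESeq2 or edgeR, whose versions are not given in the sources used here. The counting strand setting is not given in the sources used here either, so genes that overlap on opposite strands are uncertain. The deposited table holds 21428 rows and 21380 gene identifiers, 34 of which occur more than once and were used once. Its library columns hold a signal in normalized counts, that is, read counts the authors divided by one size factor per library. Dividing each column by its smallest step gave whole reads for 100% of values at a tolerance of 0.1. The table also holds a log2 fold change and an adjusted p-value that the authors computed for one comparison, which the header does not name. Median absolute differences from ratios of group means were 0.00254 for IL-4 against untreated over both genotypes, 0.4 for IFN-gamma against untreated, 0.494 for IFN-gamma against IL-4 and 0.226 for KO against WT. Group columns of the table were not used, because one of them, named for KO with IL-4, stands beside the WT libraries with IL-4. FPKM values, which the notes mention, were not used here.

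Library totals of recovered reads ran from 9.77 to 49.5 M. Normalized columns summed to 27.0 M (KO untreated replicate 2) up to 35.4 M (KO IFN-gamma replicate 1), so counts are comparable within a gene but not as shares across treatments. Intervals (95%, exact) and floors (3 counts over a group) cover counting error only.

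Genes with a normalized count of at least 10 in at least 3 of the 18 libraries were kept, 14288 in all. Log2 of the normalized count plus a pseudocount of 1 was fitted with limma 3.58.1 in R 4.3.3, with a mean for each of the 6 groups, 12 residual degrees of freedom, the trend option and moderated two-sided tests. P-values were adjusted by Benjamini and Hochberg over all genes tested, and an adjusted p under 0.05 was called. The comparisons were KO against WT in each treatment, IFN-gamma and IL-4 against untreated in each genotype, the difference of each response between genotypes (interaction), and KO against WT on 6 animal means over the 3 treatments. Comparisons, tests, gene lists and alternatives were chosen before the data were examined, apart from those stated as chosen later.

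Of 39 gene lists fixed in advance (784 genes, 697 of them in the table), 35 with at least 4 measured genes were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. The estimated-correlation form of camera and fry, a self-contained directional test, were alternatives. A list that passes a camera test ranks above or below other genes, and its genes need not pass singly. Lists shared some genes.

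Genes were named by a rule fixed in advance. It takes Ldha and Ldhb. It takes up to 10 higher and 10 lower genes with the largest change among called genes with a mean of at least 100 in the higher group and no overlap between the libraries of both groups (for responses, the call and the mean only), leaving out unnamed gene models and antigen-receptor segments. Where none qualifies, it takes the 5 genes with the smallest adjusted p, stated as not passing. From each list that passes it takes up to 4 called genes with the smallest adjusted p. It also takes the markers Nos2, Cxcl9, Irf1, Arg1, Retnla, Chil3 and Mrc1 in the polarization and the KO against WT comparisons. The text names a part of these, and genes chosen after their values were seen are stated as such. Identifiers and positions are those of the deposited table, of which 99.9% were matched to GENCODE M21 and 99.2% of these had the same position.

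The same animal codes occur in each treatment. After subtraction of group means, the 18 pairs of libraries of one animal in different treatments correlated across genes at r = 0.0036 to 0.24 (genes are not independent replicates), 13 of them above 0.1, and in 14 pairs the own animal correlated best. KO and WT animals with the same replicate number correlated at -0.21 to 0.10, so that number joins different animals and was used as a block only in an alternative. No pair of replicates was a duplicate: the chi-square per gene between replicates was 4.72 to 67.4.

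Alternatives changed one choice at a time: a pseudocount of 0.5 or 5, no filter on low values, a mean of at least 50, TMM-type factors, quantile normalization, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, only the libraries compared, a replicate block, the animal as a random block, each library left out in turn, and a log2 change of at least 1. A group with 1 library left out keeps 2, and their spread is pooled over the groups. A stromal marker score as a covariate, the macrophage identity list without Lyz2, and the immediate early list with each library left out in turn, were added after seeing the data.

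The steps were tested on simulated data drawn from a negative binomial model of these libraries, with known changes in genes of mean at least 50. For KO against WT in untreated cells, 68.7, 88.1 and 97% of genes changed 1.5-, 2- and 4-fold were recovered, with 5.06% false among the calls (14097 genes). For IFN-gamma against untreated in WT these were 61.2, 89.6 and 97%, with 2.37% false (14025 genes). For the difference of IFN-gamma responses they were 29.9, 80.6 and 95.5%, with 5.52% false (14101 genes). Where both genotypes carried equal folds of their means, 25.4% of the calls on the difference of IFN-gamma responses were false (14102 genes). These were 47 calls, of which 21 had a mean under 50. In each simulation 67, 67 and 66 of the genes tested carried the 1.5-, 2- and 4-fold changes. The false shares depend on these numbers and do not carry over to the real comparisons. For camera of limma in the simulated untreated comparison (14100 genes), a list shifted 1.5-fold passed, and 5 of 200 random lists fell under 0.05.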

Results

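Messenger RNA was sequenced from macrophages grown out of the femoral bone marrow of wild-type (WT) mice and of mice knocked out for Ldha (KO). The gene encodes the A chain of lactate dehydrogenase, the enzyme that interconverts pyruvate and lactate. After 7 days in macrophage colony-stimulating factor, cells were left untreated or exposed for 24 h to interferon gamma (IFN-gamma), a signal of classical activation, or to interleukin 4 (IL-4), a signal of alternative activation. Each of the 6 groups held 3 libraries from separate animals, 18 libraries in all, and each of the 6 animals gave a library to each treatment. Between 9.77 M reads (WT IL-4 replicate 2) and 49.5 M reads (WT IL-4 replicate 3) were assigned to genes, with a median of 30.9 M reads. The share of reads from the mitochondrial genome was 1.95 to 2.17% in untreated, 0.952 to 1.38% in IFN-gamma and 1.5 to 1.92% in IL-4 libraries. Values are means ± SD of normalized counts (n = 3), changes are log2 fold changes ± SE from limma, and 14288 genes were tested.

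The first question was how much Ldha transcript the KO cells held. Ldha (ENSMUSG00000063229.15, GRCm38 chromosome 7, 46841475 to 46855627, plus strand) fell from 11620 ± 796 to 2327 ± 238 in untreated cells, from 37280 ± 1430 to 9543 ± 507 with IFN-gamma and from 23850 ± 1160 to 4183 ± 67.8 with IL-4. KO libraries thus held 20, 25.6 and 17.5% of the WT Ldha counts. The highest KO library lay below the lowest WT library in each treatment (2591 against 10710, 10120 against 36200 and 4226 against 22900). Counts cover the whole gene, so whether these transcripts were intact, or came from some cells only, was not tested. The changes were -2.32 ± 0.0761, -1.97 ± 0.0761 and -2.51 ± 0.0761, with a highest adjusted p of 2.29e-11. Ldhb, the B chain of the same enzyme, stood at 193 ± 27.6 in WT and 146 ± 17.6 in KO untreated cells and did not pass in any treatment (-0.39, -0.26 and -0.49, adjusted p = 0.375, 0.29 and 0.107). Its KO mean was 75.8, 83.6 and 71% of the WT mean, and the highest KO library lay just below the lowest WT library in each treatment (164.9 against 167.3, 57.15 against 58.62 and 192.5 against 196.7). In the IL-4 cells Ldhb passed with DESeq2 (adjusted p = 0.0327) and without WT IL-4 replicate 2 (0.0396).

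A change larger than that of Ldha was seen in Lyz2, the lysozyme gene that macrophages transcribe heavily (chromosome 10, 117277331 to 117282321). Its level was 631600 ± 64800 in WT and 784 ± 92.2 in KO untreated cells, 218700 ± 16700 and 189 ± 15.6 with IFN-gamma, and 363400 ± 15300 and 482 ± 49.6 with IL-4. KO means were 0.124, 0.0866 and 0.133% of the WT means, changes of -9.65 ± 0.102, -10.17 ± 0.102 and -9.56 ± 0.102. Its near-identical neighbour Lyz1, with which it can share reads, was also lower in KO by means (348 against 180.3, 122 against 89.9 and 192 against 152). KO and WT cells thus differed in Lyz2 as well as Ldha. The comparisons below therefore cannot tell loss of Ldha from loss of Lyz2 or from another difference between the KO and WT animals.

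**Figure D1:**
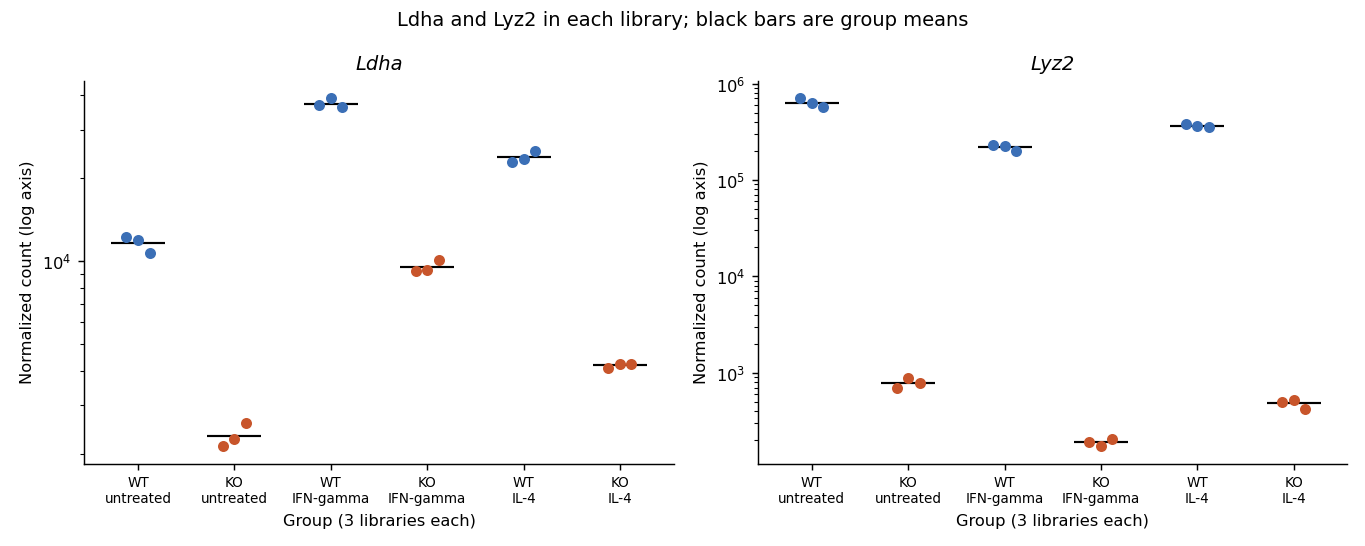
Normalized counts of Ldha and Lyz2 on a log axis in each of the 18 libraries, with 3 points per group and a black bar at the group mean. KO group means were 17.5 to 25.6% of the WT means for Ldha and 0.0866 to 0.133% for Lyz2.

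In untreated macrophages the question was what differed in KO cells without a polarizing signal. Most listed genes of the antioxidant program driven by the transcription factor NRF2 were higher in KO. Nqo1, a quinone reductase, rose from 76.6 ± 15.8 to 536 ± 151 (2.77 ± 0.257, adjusted p = 5.34e-06), and Slc7a11, which imports cystine for glutathione, rose by 2.87 ± 0.341. The peroxiredoxin-repairing enzyme Srxn1 rose by 1.42 ± 0.109, the NADPH-producing malic enzyme Me1 by 1.54 ± 0.128, glutathione reductase (Gsr) by 0.81 ± 0.0677 and catalase (Cat) by 1.05 ± 0.0936, all with adjusted p of at most 0.00012. Among NRF2 targets 14 of 18 measured genes were higher, 0 lower and 4 did not pass, with 15 called when adjusted over the list alone. Camera gave an adjusted p of 2.15e-38, with adjusted p = 0.00688 with an estimated correlation. In the pentose phosphate pathway, which also yields NADPH, Taldo1 (0.86 ± 0.106), Pgd (0.77 ± 0.106) and G6pdx (0.42 ± 0.067) were higher. In that list 3 of 8 measured genes were higher, 0 lower and 5 did not pass, with 4 called when adjusted over the list alone. By camera the adjusted p was 0.041, with adjusted p = 0.385 with an estimated correlation. Taldo1 belongs to both lists.

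Some genes of sugar and amino acid use were higher as well. The glucose transporter Slc2a1 rose by 0.59 ± 0.0917 and the pyruvate kinase gene Pkm by 0.66 ± 0.11 (highest adjusted p = 0.00308). In the glycolysis list, which leaves Ldha out, 6 of 18 measured genes were higher, 0 lower and 12 did not pass, with 9 called when adjusted over the list alone. Its camera adjusted p was 1.17e-07, and 0.221 with an estimated correlation. Phgdh, which starts serine synthesis from a glycolytic intermediate, rose by 1.32 ± 0.166 and the stress factor Atf5 by 1.01 ± 0.13. Among genes of ATF4 and amino acid stress 4 of 26 measured genes were higher, 0 lower and 22 did not pass, with 8 called when adjusted over the list alone. Camera gave adjusted p = 1.54e-07, and 0.221 with an estimated correlation. Lists of lactate and pyruvate handling, cytosolic NADH shuttles and the TCA cycle did not pass (camera adjusted p = 0.903, 0.571 and 0.203, with 4, 1 and 1 genes called when adjusted over the list alone).

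Large increases were also seen outside these lists. Serpinb9b, a granzyme-inhibitor family member, rose by 4.42 ± 0.395, Met, the receptor of hepatocyte growth factor, by 3.41 ± 0.42, and Ednrb, an endothelin receptor, by 3.19 ± 0.234 (from 63.5 ± 11.6 to 585 ± 70.7). Ndrg4 (3.16), Uchl1 (2.81), Flrt3 (2.62) and Procr (2.15) followed, all with adjusted p of at most 0.00177. Lower in KO were the chemokine genes Ccl6 (-1.13 ± 0.131) and Ccl5 (-1.06 ± 0.179), the chemerin receptor Cmklr1 (-0.98 ± 0.156) and the inhibitory Fc receptor Fcgr2b (-0.96 ± 0.132). Among phagocytic and scavenger receptors 1 of 29 measured genes were higher, 4 lower and 24 did not pass, with 11 called when adjusted over the list alone. Its camera adjusted p was 0.00108, and 0.221 with an estimated correlation. Apolipoprotein E (Apoe) was lower by the full set of libraries (-1.60 ± 0.344, adjusted p = 0.0188) but did not pass without WT replicate 2 (0.101), WT replicate 3 (0.112), KO replicate 1 (0.0647) or KO replicate 3 (0.101).

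Some matrix and identity genes passed too. The collagenase gene Mmp13 (2.0 ± 0.342) was higher. In the list of extracellular matrix and remodelling 4 of 23 measured genes were higher, 0 lower and 19 did not pass, with 11 called when adjusted over the list alone. The camera adjusted p was 0.000452 and adjusted p = 0.221 with an estimated correlation. The list of markers of stromal cells and fibroblasts, a cell type that marrow cultures can carry, was shifted up beside it. Col1a1 stood at 119 ± 63.2 in WT and 440.1 ± 250 in KO, and in that list 0 of 15 measured genes were higher, 0 lower and 15 did not pass, with 10 called when adjusted over the list alone. Camera gave an adjusted p of 1.08e-07, with adjusted p = 0.289 with an estimated correlation. For macrophage identity 1 of 18 measured genes were higher, 3 lower and 14 did not pass, with 4 called when adjusted over the list alone. By camera the adjusted p was 0.000352, with adjusted p = 0.221 with an estimated correlation. Without Lyz2 the identity list did not pass (adjusted p = 0.0557). The cell cycle list passed with 1 of 31 genes higher (2 adjusted over the list alone, camera adjusted p = 0.00412), and adjusted p = 0.543 with an estimated correlation. With the stromal score as a covariate, chosen after seeing the data, the cell cycle list had adjusted p = 0.1 and the pentose phosphate list 0.322, whereas NRF2 targets kept 5.17e-34. The covariate newly called monocyte markers (up, 0.00256, from 0.0561 without it) and the nuclear-encoded respiratory chain (down, 0.02, against up and 0.151 without it). HIF targets outside glycolysis (1 higher and 1 lower of 22, 6 adjusted over the list alone, camera adjusted p = 0.0391) and cholesterol synthesis (0 called either way, 0 adjusted over the list alone, 0.041, and 0.0569 after quantile normalization) also passed, with adjusted p = 0.543 and 0.797 with an estimated correlation.

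By limma 283 genes passed in untreated cells, 208 higher and 75 lower in KO, 115 of them at least 2-fold, and 1702 had an unadjusted p under 0.05. DESeq2 called 608, edgeR 384, and a fit of the untreated libraries alone 971. The count was 127 without WT replicate 2, 129 without WT replicate 3, 135 without KO replicate 1 and 124 without KO replicate 3. None of the 7 polarization markers passed: Nos2 changed by 0.12 ± 0.25, Cxcl9 by 0.29 ± 0.747, Irf1 by -0.24 ± 0.109, Arg1 by -1.21 ± 0.478 and Mrc1, the mannose receptor gene, by -0.85 ± 0.249 (adjusted p = 0.942, 0.95, 0.397, 0.277 and 0.0999). Mrc1 passed with edgeR (0.0274), DESeq2 (0.00394) and the untreated libraries alone (0.0171). Chil3 had 1 read over the WT libraries and 6 over the KO libraries, a ratio of 6.29 (95% interval 0.763 to 289), and Retnla was listed at 0 in both. Without KO replicate 1 the Nos2 change was -0.038, and without WT replicate 2 the Cxcl9 change was -0.21.

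Under IFN-gamma the question was how classically activated KO macrophages differed from WT. The classical markers Nos2 and Cxcl9 did not pass over the full set of libraries. Nos2, the inducible nitric oxide synthase, stood at 121300 ± 10400 in WT and 172200 ± 15000 in KO (0.50 ± 0.25, adjusted p = 0.145). The chemokine gene Cxcl9 stood at 117100 ± 4980 and 71450 ± 3930 (-0.71 ± 0.747, adjusted p = 0.52). Both passed with the IFN-gamma libraries alone (adjusted p = 0.0281 for Nos2 and 0.00361 for Cxcl9), and Cxcl9 also with edgeR (0.00915). Irf1 lay at the threshold (-0.30 ± 0.109, adjusted p = 0.05, and 0.223 with the stromal score as a covariate). It did not pass after quantile normalization (0.134), with a pseudocount of 0.5 (0.051), with no filter on low values (0.0628) or with the IFN-gamma libraries alone (0.0829). Nor did it pass without WT IFN-gamma replicate 1 (0.222), WT IFN-gamma replicate 2 (0.0538), KO IFN-gamma replicate 1 (0.102), KO IFN-gamma replicate 2 (0.117) or KO IFN-gamma replicate 3 (0.087). In the list of IFN-gamma response genes 3 were higher, 5 lower and 33 of 41 did not pass (7 adjusted over the list alone, camera adjusted p = 0.849). Interleukin 1 beta (Il1b) was lower in KO, at 2751 ± 1120 against 23730 ± 15900 in WT (-3.0 ± 0.584, adjusted p = 0.00111), whereas Il12b, which encodes the p40 chain of interleukin 12, was higher, at 222 ± 82.4 against 8.32 ± 3.86 (4.59 ± 0.616). The interleukin 36 gene Il1f9 rose by 4.28 ± 0.396.

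Most NRF2 targets were again higher: Gclc, which starts glutathione synthesis, by 1.12 ± 0.0847, Srxn1 by 1.12 ± 0.109, Me1 by 1.19 ± 0.128 and the glutathione transferase Gsta3 by 3.09 ± 0.403. In the list 14 of 18 measured genes were higher, 0 lower and 4 did not pass, with 16 called when adjusted over the list alone. Its camera adjusted p was 4.37e-10, and 0.314 with an estimated correlation. Several lysosomal and osteoclast genes stood higher in KO. Cathepsin K (Ctsk) was at 297 ± 60.4 in KO and 49.4 ± 9.27 in WT (2.56 ± 0.195), the integrin gene Itgb3 at 195 ± 18.9 and 11.1 ± 7.43 (4.18 ± 0.278), and the lysosomal lipase gene Lipa rose by 0.95 ± 0.0898. In the lysosome list 15 of 26 measured genes were higher, 2 lower and 9 did not pass, with 17 called when adjusted over the list alone. Camera gave adjusted p = 4.74e-05, and 0.592 with an estimated correlation. In the osteoclast list 5 of 9 measured genes were higher, 0 lower and 4 did not pass, with 6 called when adjusted over the list alone. Its camera adjusted p was 0.0391, and 0.314 with an estimated correlation. The stromal score as a covariate brought it to 0.0724. Several immediate early genes, which signal transduction induces within minutes, were lower: Nr4a1 by -2.0 ± 0.195, Zfp36 by -1.0 ± 0.105, Ier2 by -0.90 ± 0.103 and Btg2 by -0.75 ± 0.0752. In that list 0 of 17 measured genes were higher, 10 lower and 7 did not pass, with 11 called when adjusted over the list alone. The camera adjusted p was 3.68e-06, and 0.135 with an estimated correlation. WT IFN-gamma replicate 1 stood apart from the others of its group (chi-square per gene 61.09 and 67.39 against 4.717 between replicates 2 and 3), and without it 8 genes were lower (camera adjusted p = 3.07e-06, and 0.0875 with an estimated correlation). With the stromal covariate the lists of ATF4 and amino acid stress (up, 0.00306, from 0.0667 without it), macrophage identity (down, 0.0107, from 0.0667) and the respiratory chain (down, 0.0182, from 0.849) were newly called.

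Other large increases were in Ednrb (from 71.9 ± 23.4 to 2248 ± 75.5, 5.0 ± 0.234), Cdcp1 (4.83 ± 0.365), the deiodinase gene Dio2 (4.63 ± 0.355), the protease gene Htra1 (4.14 ± 0.492), Itgb8 (4.01 ± 0.259), Htr2a (3.63 ± 0.231) and Serpinb9b (3.62 ± 0.395). Other large decreases were in Cd226 (-2.88 ± 0.543), the linker histone H1f2 (-2.65 ± 0.305), Cfap126 (-2.44), Fam43a (-2.38), Slc4a11 (-2.35), Ifitm6 (-2.29) and Cass4 (-2.26). These 14 genes had adjusted p of at most 0.00135. Fosb was lower (-3.01 ± 0.783, adjusted p = 0.00845) but did not pass without WT IFN-gamma replicate 1 (0.0551), without KO IFN-gamma replicate 1 (0.0581) or with the stromal covariate (0.0866). The stromal list was shifted up here as well. In their list 3 of 15 measured genes were higher, 0 lower and 12 did not pass, with 3 called when adjusted over the list alone. Camera gave an adjusted p of 0.0338, and 0.868 with an estimated correlation. The called genes were Igfbp7 (2.44 ± 0.49), Col5a1 (2.91 ± 0.667) and Pdgfrb (1.32 ± 0.342, adjusted p = 0.0638 with the IFN-gamma libraries alone). Mrc1 was lower, at 94.6 ± 22.8 against 172 ± 77.3 (-0.77 ± 0.249, adjusted p = 0.028), and did not pass with the IFN-gamma libraries alone (0.161), with the stromal covariate (0.0629) or without WT IFN-gamma replicate 2 (0.0768), WT IFN-gamma replicate 3 (0.159) or KO IFN-gamma replicate 2 (0.139). Chil3 did not pass (0.58 ± 0.641, adjusted p = 0.543), nor did Arg1 (1.30 ± 0.478, adjusted p = 0.0506). Arg1 passed with a pseudocount of 5 (0.0384), a mean of at least 50 (0.0469), DESeq2 (0.0383), the replicate block (0.0496) and without WT IFN-gamma replicate 2 (0.0258) or WT IFN-gamma replicate 3 (0.0385). By limma 3980 genes passed, 2038 higher and 1942 lower in KO, 883 of them at least 2-fold.

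Under IL-4 the question was how alternatively activated KO macrophages differed from WT. Of the alternative-activation markers, Mrc1 was lower in KO, at 29660 ± 4250 against 59660 ± 2560 (-1.02 ± 0.249, adjusted p = 0.0209, and 0.0938 without KO IL-4 replicate 1). The arginase gene Arg1 (5081 ± 1190 against 5670 ± 1570, -0.15 ± 0.478), Chil3 (-0.29 ± 0.641) and Retnla (479.7 ± 81.3 against 1067 ± 674, -0.89 ± 0.439) did not pass (adjusted p = 0.894, 0.836 and 0.251). Retnla passed without WT IL-4 replicate 1 (-1.57, adjusted p = 0.0157). Leaving out 1 library turned the sign of Arg1 (0.053 without WT IL-4 replicate 1 and 0.047 without KO IL-4 replicate 2) and of Chil3 (0.19 without KO IL-4 replicate 2). Nos2 was higher in KO, at 1948 ± 215 against 436 ± 250 (2.30 ± 0.25, adjusted p = 2.81e-05), a level still far below that under IFN-gamma. In the IL-4 response list 2 genes were higher, 1 lower and 32 of 35 did not pass (3 adjusted over the list alone, camera adjusted p = 0.819).

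Most NRF2 targets were higher in IL-4 cells too. Nqo1 stood at 1028 ± 155 in KO and 168 ± 24.2 in WT (2.61 ± 0.257), Gsr rose by 1.12 ± 0.0677, Srxn1 by 1.55 ± 0.109, Me1 by 1.82 ± 0.128, Gclc by 1.07 ± 0.0847, Slc7a11 by 2.56 ± 0.341 and Gsta3 by 2.48 ± 0.403 (highest adjusted p = 0.00126). In the list 14 of 18 measured genes were higher, 0 lower and 4 did not pass, with 16 called when adjusted over the list alone. By camera the adjusted p was 4.62e-27, and 0.0292 with an estimated correlation. Some amino acid stress genes were also higher, with Atf5 at 1.35 ± 0.13, Phgdh at 1.33 ± 0.166 and Atf4 itself at 0.50 ± 0.0836. In that list 7 of 26 measured genes were higher, 0 lower and 19 did not pass, with 9 called when adjusted over the list alone. Its camera adjusted p was 3.29e-07, and 0.314 with an estimated correlation. The glycolysis and pentose phosphate lists did not pass here (camera adjusted p = 0.0838 and 0.0609, with 2 and 4 genes called when adjusted over the list alone).

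Receptors for the Fc part of antibodies were lower in KO: Fcgr4 by -1.14 ± 0.137, Fcgr3 by -0.64 ± 0.0847 and Fcgr2b by -0.90 ± 0.132 (highest adjusted p = 0.000519). Among phagocytic and scavenger receptors 1 of 29 measured genes were higher, 10 lower and 18 did not pass, with 16 called when adjusted over the list alone. Camera gave adjusted p = 0.000191, and 0.103 with an estimated correlation. For macrophage identity 0 of 18 measured genes were higher, 8 lower and 10 did not pass, with 11 called when adjusted over the list alone. Its camera adjusted p was 3.21e-08, and 0.0396 with an estimated correlation. Without Lyz2 the identity list had adjusted p = 2.17e-05, and 0.105 with an estimated correlation. The dendritic-cell markers Ccl22 (1.97 ± 0.302) and Ccr7 (2.53 ± 0.543) were higher, and in that list 2 of 9 measured genes were higher, 0 lower and 7 did not pass, with 3 called when adjusted over the list alone. The camera adjusted p was 0.0158, and 0.459 with an estimated correlation. Quantile normalization gave 0.0998 and the stromal covariate 0.0841. The stromal list was again shifted up. In their list 0 of 15 measured genes were higher, 0 lower and 15 did not pass, with 2 called when adjusted over the list alone. Camera gave an adjusted p of 0.00417, and 0.735 with an estimated correlation. The receptor genes Met (3.81 ± 0.42) and Ednrb (2.99 ± 0.234), Serpinb9b (3.71 ± 0.395), the retinol carrier Rbp4 (3.29 ± 0.527), Uchl1 (2.70 ± 0.2) and Ndrg4 (2.60 ± 0.387) were among the large increases. Kcnj10 (-1.73 ± 0.221) and Ifitm6 (-1.30 ± 0.171) were among the decreases. Apoe (-1.71 ± 0.344), Itga9 (-1.73 ± 0.345), Cd4 (-1.61 ± 0.334) and Cdcp1 (2.46 ± 0.365) passed in the full set but not with the IL-4 libraries alone (adjusted p = 0.0846, 0.0768, 0.0601 and 0.0715).

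Several lists passed in IL-4 cells with few called genes. The heat shock list was shifted up, Hsph1 (0.57 ± 0.0737) was called, and in that list 4 of 19 measured genes were higher, 0 lower and 15 did not pass, with 9 called when adjusted over the list alone. By camera the adjusted p was 0.0487, with adjusted p = 0.459 with an estimated correlation. TMM scaling gave 0.0503 and the stromal covariate 0.0757. In the cell cycle list 3 of 31 measured genes were higher, 0 lower and 28 did not pass, with 6 called when adjusted over the list alone. Its camera adjusted p was 0.00103, and 0.459 with an estimated correlation. In the nuclear-encoded respiratory chain 0 of 47 measured genes were higher, 0 lower and 47 did not pass, with 0 called when adjusted over the list alone. Against other genes, camera gave 0.00251, with adjusted p = 0.735 with an estimated correlation, and the stromal covariate gave 0.817. Other lists were shifted down in KO. For cholesterol synthesis and uptake 0 of 23 measured genes were higher, 2 lower and 21 did not pass, with 2 called when adjusted over the list alone. As a set its camera adjusted p was 0.0487 and adjusted p = 0.735 with an estimated correlation, and TMM scaling gave 0.0503, quantile normalization 0.083 and the stromal covariate 4.63e-05. For the type I interferon response 1 of 25 measured genes were higher, 1 lower and 23 did not pass, with 2 called when adjusted over the list alone. The camera adjusted p was 0.0158 and adjusted p = 0.735 with an estimated correlation, and the stromal covariate gave 0.231. For inflammatory cytokines and chemokines 0 of 31 measured genes were higher, 2 lower and 29 did not pass, with 8 called when adjusted over the list alone. Camera gave an adjusted p of 0.0487, with adjusted p = 0.459 with an estimated correlation, and TMM scaling gave 0.0503, quantile normalization 0.0621 and the stromal covariate 0.121. By limma 941 genes passed in IL-4 cells, 494 higher and 447 lower in KO, 276 of them at least 2-fold, and 3121 had an unadjusted p under 0.05. The IL-4 libraries alone gave 128, of which 126 were among the 941, and the count was 497 without KO IL-4 replicate 1. Replicates differed more here than untreated. The chi-square per gene was 46.79 to 66.32 in WT and 26.72 to 60.11 in KO with IL-4, against 11.58 to 21.86 in the untreated groups. The main fit pools the spread over all 6 groups, so its p-values for IL-4 rest in part on groups whose replicates differed less.

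Changes shared by the treatments were counted next. In all 3 treatments 99 genes were higher and 29 lower in KO. Untreated and IL-4 cells shared 132 higher and 55 lower genes, where independent lists of these sizes would share 7.19 and 2.35, and no gene passed in opposite directions. Untreated and IFN-gamma cells shared 127 higher and 35 lower genes (29.7 and 10.2 for independent lists), with 12 and 7 opposite. IFN-gamma and IL-4 cells shared 283 and 270 (70.5 and 60.8), with 18 and 10 opposite. The same 6 animals supplied all 3 treatments, so these overlaps are not independent repeats. With each animal counted once as the mean of its 3 libraries, 1618 genes passed by limma, 904 higher and 714 lower in KO. Among them were Il1f9 (4.26 ± 0.263), Serpinb9b (3.92 ± 0.306), Ednrb (3.73 ± 0.143), Cdcp1 (3.38 ± 0.266), Met (3.29 ± 0.312), Uchl1 (2.93 ± 0.132), Slc7a11 (2.59 ± 0.243) and Atf5 (1.47 ± 0.0945), and on the lower side Lyz2 (-9.79 ± 0.0646), Ldha (-2.27 ± 0.0567) and Ifitm6 (-1.39 ± 0.126). For NRF2 targets 16 of 18 measured genes were higher, 0 lower and 2 did not pass, with 16 called when adjusted over the list alone. By camera the adjusted p was 6.61e-18, with adjusted p = 0.379 with an estimated correlation. The animal-mean count was 985 without WT replicate 2, 743 without WT replicate 3, 748 without KO replicate 1, 910 without KO replicate 2, 959 without KO replicate 3 and 869 with edgeR. Among the 35 gene lists, camera calls that held with an estimated correlation in the KO against WT comparisons were NRF2 targets in untreated and IL-4 cells and macrophage identity in IL-4 cells, the last of which did not hold without Lyz2 (0.105).

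**Figure D2:**
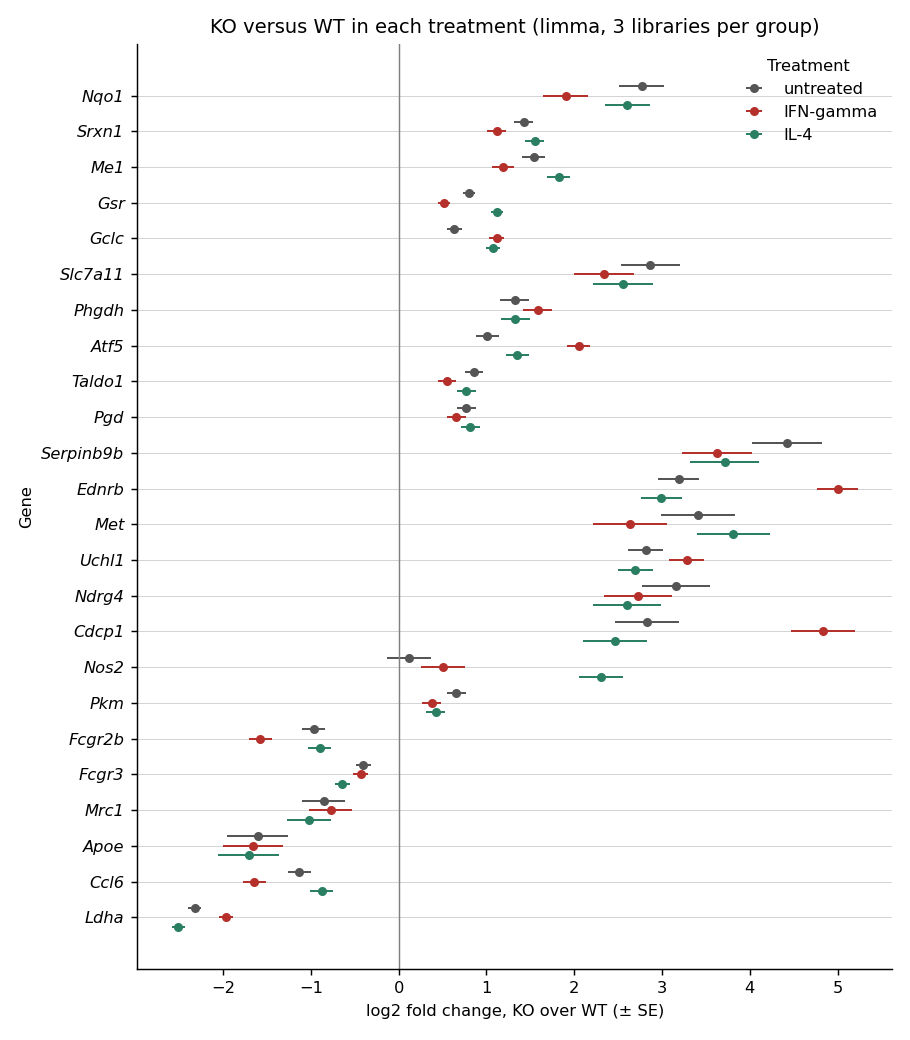
Log2 fold change of KO over WT (points) with its SE (bars) for 24 genes in untreated, IFN-gamma and IL-4 macrophages, 3 libraries per group. Srxn1 rose by 1.42, 1.12 and 1.55 and Ldha fell by 2.32, 1.97 and 2.51 in these treatments.

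The response to IFN-gamma within each genotype showed whether classical activation took place. Cxcl9 rose from 23.7 ± 12.7 to 117100 ± 4980 in WT and from 26.8 ± 8.06 to 71450 ± 3930 in KO (12.37 ± 0.747 and 11.37 ± 0.747). Nos2 rose by 11.54 ± 0.25 and 11.93 ± 0.25, Irf1 by 5.20 ± 0.109 and 5.14 ± 0.109, and the GTPase genes Gbp2 by 8.96 ± 0.17 and 9.24 ± 0.17, Gbp4 by 11.73 and 11.0 and Iigp1 by 10.96 and 11.53. Cxcl11 had 3 reads over the untreated WT libraries, a ratio of 8250 (95% interval 2820 to 40000), and 2 over the untreated KO libraries, a ratio of 4990 (95% interval 1380 to 41200). Gbp2, Serpina3f and Serpina3g (11.82 and 11.39 in WT) have near-identical relatives, so their reads are uncertain between copies. Of the IFN-gamma response list, all 41 measured genes were higher in both genotypes, with 0 lower, 0 not passing and 41 called when adjusted over the list alone (camera adjusted p = 2.92e-28 in WT and 8.65e-33 in KO, adjusted p = 0.0398 and 0.0223 with an estimated correlation). Most listed antigen-presentation genes rose, with Cd74 at 4.38 ± 0.188 and 4.13 ± 0.188, Cd40 at 6.03 ± 0.154 and 6.38 ± 0.154 and Tap2 at 2.67 ± 0.0877 and 2.46 ± 0.0877. For class I presentation the list gave 20 higher, 0 lower and 0 not passing in WT and 20, 0 and 0 in KO (20 and 20 called when adjusted over the list alone). Camera gave adjusted p = 2.67e-14 in WT and 4.04e-17 in KO, with adjusted p = 0.0992 and 0.0676 with an estimated correlation. For class II presentation, which holds Cd74, it gave 13 higher, 0 lower and 1 not passing in WT and 12, 0 and 2 in KO (13 and 12 called when adjusted over the list alone). By camera the list had adjusted p = 7.14e-09 and 8.52e-09, with adjusted p = 0.0992 and 0.091 with an estimated correlation.

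IFN-gamma also changed metabolism and growth genes. Ldha rose by 1.68 ± 0.0761 in WT and 2.04 ± 0.0761 in KO, and Ldhb fell by 1.63 ± 0.176 and 1.5 ± 0.176. Most glycolysis genes rose, such as Slc2a1 (2.94 ± 0.0917 and 2.52 ± 0.0917), Hk3 (2.59 ± 0.0864 and 2.54 ± 0.0864) and Pfkfb3 (3.06 ± 0.106 and 3.26 ± 0.106). The list had 16 higher, 2 lower and 0 not passing in WT and 15, 2 and 1 in KO (18 and 17 called when adjusted over the list alone). Camera adjusted p-values were 3.67e-09 in WT and 3.61e-09 in KO, with adjusted p = 0.132 and 0.154 with an estimated correlation. Proliferation genes fell, with Ube2c at -5.23 ± 0.221 and -5.29 ± 0.221, Ccna2 at -4.94 ± 0.257 and -5.21 ± 0.257 and Rrm2 at -4.88 ± 0.211 and -4.09 ± 0.211. In the cell cycle list there were 1 higher, 29 lower and 1 not passing in WT and 2, 29 and 0 in KO (30 and 31 called when adjusted over the list alone). Camera gave adjusted p = 1.83e-10 in WT and 1.77e-12 in KO, with adjusted p = 0.0992 and 0.0676 with an estimated correlation. Mrc1 dropped from 12240 ± 1870 to 172 ± 77.3 in WT and from 6766 ± 1020 to 94.6 ± 22.8 in KO (-6.25 ± 0.249 and -6.17 ± 0.249), and Hpgd by -7.34 ± 0.537 and -7.18 ± 0.537. Cmah was at 0 reads with IFN-gamma in WT, at least 292-fold lower, against a floor of 3 counts over the group. Mitochondrially encoded transcripts, a sign of RNA composition, moved with the treatment: mt-Nd1 fell by 1.11 ± 0.127 and 1.24 ± 0.127, and their list had 0 higher, 7 lower and 2 not passing in WT and 0, 7 and 2 in KO (7 and 7 called when adjusted over the list alone). By camera the list had adjusted p = 0.0108 and 0.0274, with adjusted p = 0.465 and 0.579 with an estimated correlation. Most dendritic-cell genes rose in both, such as Clec9a (7.53 ± 0.555 and 6.88 ± 0.555), and their list had 7 higher, 1 lower and 1 not passing in WT and 6, 0 and 3 in KO (8 and 7 called when adjusted over the list alone). Camera adjusted p-values were 0.00193 in WT and 0.00148 in KO, with adjusted p = 0.151 and 0.154 with an estimated correlation.

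By limma 8922 genes passed with IFN-gamma in WT (4481 higher, 4441 lower, 3911 at least 2-fold) and 7970 in KO (4043 higher, 3927 lower, 3280 at least 2-fold). The genotypes shared 3383 higher and 3161 lower genes (1268 and 1221 for independent lists), with 48 and 40 opposite. Arg1 did not pass in WT (-0.049 ± 0.478, adjusted p = 0.936) and rose in KO from 1.41 ± 1.31 to 10.9 ± 2.72 (2.46 ± 0.478, adjusted p = 0.00027). The WT value turned positive with edgeR (0.16) and DESeq2 (0.18), after quantile normalization (0.16) or with a pseudocount of 5 (0.032), and without WT untreated replicate 1 (0.081), WT untreated replicate 2 (0.035) or WT IFN-gamma replicate 1 (0.58). Chil3 did not pass in either genotype (0.53 ± 0.641 and 0.34 ± 0.641, adjusted p = 0.491 and 0.677), with -0.31 in WT without WT IFN-gamma replicate 3 and -0.20 in KO without KO untreated replicate 1. Retnla was listed at 0 in the untreated and the IFN-gamma libraries of both genotypes.

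**Figure D3:**
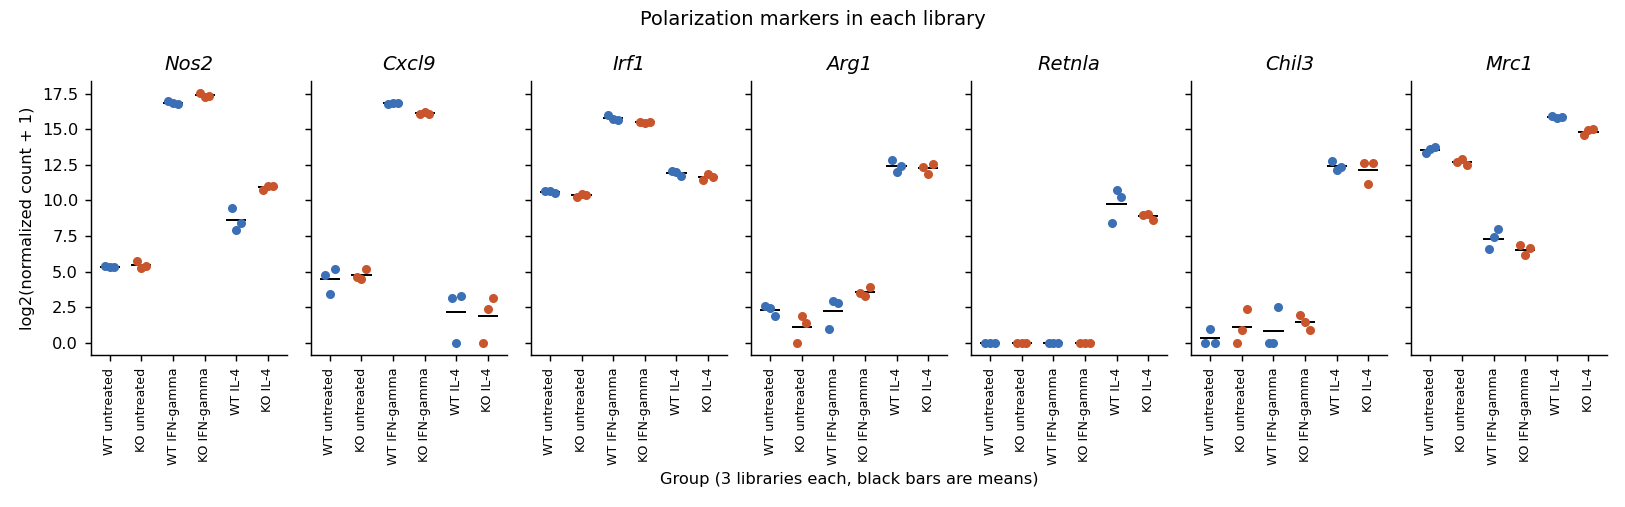
Log2 of the normalized count plus 1 for 7 polarization markers in each of the 18 libraries, with 3 points per group and a black bar at the mean of the log2 values. Nos2 rose by 11.54 in WT and 11.93 in KO with IFN-gamma, and Arg1 by 10.14 and 11.20 with IL-4.

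The response to IL-4 within each genotype showed whether alternative activation took place. Arg1 rose from 4 ± 1.2 to 5670 ± 1570 in WT and from 1.41 ± 1.31 to 5081 ± 1190 in KO (10.14 ± 0.478 and 11.20 ± 0.478). Chil3 had 1 read over the untreated WT libraries, a ratio of 21000 (95% interval 3760 to 828000), and rose by 11.05 ± 0.641 in KO. Retnla was at 0 without IL-4 and at least 1170-fold higher in WT and 537-fold in KO, against a floor of 3 counts over the group. Mrc1 rose by 2.30 ± 0.249 and 2.13 ± 0.249, the lectin gene Mgl2 by 7.42 ± 0.351 and 7.54 ± 0.351, and Flt1, a receptor of vascular growth factors, by 7.79 ± 0.276 and 8.20 ± 0.276. In the IL-4 response list there were 30 higher, 1 lower and 4 not passing in WT and 28, 1 and 6 in KO (33 and 30 called when adjusted over the list alone). Camera gave adjusted p = 8.12e-28 in WT and 3.43e-26 in KO, with adjusted p = 1.39e-06 and 1.95e-06 with an estimated correlation. Nos2 rose as well, by 3.28 ± 0.25 in WT and 5.46 ± 0.25 in KO, and Irf1 by 1.33 ± 0.109 and 1.25 ± 0.109. Cxcl9 fell by 2.33 ± 0.747 in WT (adjusted p = 0.0248) and by 2.92 ± 0.747 in KO (0.00612). The WT call was lost with the WT untreated and IL-4 libraries alone (0.117) and without WT untreated replicate 1 (0.0734), WT untreated replicate 3 (0.106) or WT IL-4 replicate 2 (0.149).

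Most listed genes of lipid synthesis and protein folding rose with IL-4. The cholesterol-synthesis genes Hmgcs1 (1.23 ± 0.109 and 1.27 ± 0.109), Lss (1.31 ± 0.113 and 1.24 ± 0.113) and Nsdhl (1.12 ± 0.103 and 1.08 ± 0.103) were higher. Their list had 23 higher, 0 lower and 0 not passing in WT and 23, 0 and 0 in KO (23 and 23 called when adjusted over the list alone). By camera the list had adjusted p = 8.27e-16 and 9.57e-15, with adjusted p = 0.104 and 0.103 with an estimated correlation. The desaturase genes Scd1 (3.29 ± 0.264 and 2.84 ± 0.264) and Scd2 (2.26 ± 0.18 and 2.42 ± 0.18) were higher, and the fatty acid synthesis list had 10 higher, 0 lower and 2 not passing in WT and 9, 0 and 3 in KO (10 and 9 called when adjusted over the list alone). Camera adjusted p-values were 8.26e-07 in WT and 1.42e-06 in KO, with adjusted p = 0.0426 and 0.046 with an estimated correlation. The chaperone genes Pdia4 (1.28 ± 0.0657 and 1.25 ± 0.0657) and Hsph1 (0.94 ± 0.0737 and 1.19 ± 0.0737) rose, and the heat shock list had 13 higher, 0 lower and 6 not passing in WT and 15, 0 and 4 in KO (13 and 15 called when adjusted over the list alone). Camera gave adjusted p = 5.46e-08 in WT and 3.29e-10 in KO, with adjusted p = 0.0237 and 0.00819 with an estimated correlation. Ldha rose by 1.04 ± 0.0761 and 0.85 ± 0.0761, while Ldhb did not pass (0.34 ± 0.176 and 0.25 ± 0.176, adjusted p = 0.158 and 0.325, and 0.0493 in WT without WT IL-4 replicate 2). Most osteoclast genes also rose, with Itgb3 at 2.34 ± 0.278 and 2.19 ± 0.278 and Atp6v0d2 at 2.31 ± 0.169 and 3.02 ± 0.169. Their list had 7 higher, 1 lower and 1 not passing in WT and 7, 2 and 0 in KO (9 and 9 called when adjusted over the list alone). By camera the list had adjusted p = 0.000393 and 0.000553, with adjusted p = 0.0426 and 0.046 with an estimated correlation. Megakaryocyte and erythroid genes, among them Tfrc (1.29 ± 0.256 and 1.24 ± 0.256), had 3 higher, 0 lower and 1 not passing in WT and 3, 0 and 1 in KO (3 and 3 called when adjusted over the list alone). Camera adjusted p-values were 0.0201 in WT and 0.0293 in KO, with adjusted p = 0.104 and 0.103 with an estimated correlation.

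Among genes that fell with IL-4, the fractalkine receptor Cx3cr1 changed by -4.47 ± 0.36 in WT and -5.07 ± 0.36 in KO, Cmah by -5.74 ± 0.439 and -6.32 ± 0.439, Cxcr3 by -5.31 ± 0.784 and -5.16 ± 0.784 and Adgre4 by -4.66 ± 0.741 and -4.25 ± 0.741. Pilrb1 (-5.33 and -4.38) and Pilrb2 (-4.81 and -4.26) are near-identical copies and uncertain as single genes. The proliferation genes Rrm2 (-2.05 ± 0.211 and -1.94 ± 0.211) and Top2a (-1.89 ± 0.211 and -1.85 ± 0.211) fell, and the cell cycle list had 0 higher, 28 lower and 3 not passing in WT and 0, 28 and 3 in KO (28 and 28 called when adjusted over the list alone). Camera gave adjusted p = 4.36e-16 in WT and 9.71e-15 in KO, with adjusted p = 0.0264 and 0.0375 with an estimated correlation. By limma 4332 genes passed in WT (2332 higher, 2000 lower, 1304 at least 2-fold) and 4318 in KO (2253 higher, 2065 lower, 1282 at least 2-fold). They shared 1790 higher and 1414 lower genes (368 and 289 for independent lists), with 0 opposite. The calls that held with an estimated correlation in the polarization comparisons were IFN-gamma response genes with IFN-gamma, and IL-4 response, fatty acid synthesis, heat shock and unfolded protein response, cell cycle and osteoclast genes with IL-4, each in both genotypes. One fold change and adjusted p per gene was deposited by the authors for a comparison they do not name, closest to IL-4 against untreated over both genotypes, with 5526 of 18059 genes under 0.05. That table gives Arg1 at 10.98, Chil3 at 12.39, Mrc1 at 2.23 and Ldha at 1.01 (adjusted p = 0.21).

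Whether the response to IFN-gamma differed in KO cells was tested as the difference of the responses, KO minus WT. Some osteoclast and lysosomal genes differed upward. Itgb3 fell by 5.90 ± 0.278 in WT from 662 ± 187 to 11.1 ± 7.43, against 952 ± 156 to 195 ± 18.9 in KO, a difference of 3.63 ± 0.393 (adjusted p = 3.42e-05). The difference was 2.47 ± 0.276 for Ctsk, 0.80 ± 0.127 for Lipa and 0.53 ± 0.122 for the lysosomal glucosidase gene Gaa. Outside both lists it was 4.27 ± 0.501 for Dio2, 3.65 ± 0.695 for Htra1, 3.40 ± 0.374 for the lipid chaperone Fabp4 and 3.08 ± 0.39 for Dusp9 (highest adjusted p of these 7 genes 0.0113). In the lysosome list 9 of 26 measured genes were higher, 1 lower and 16 did not pass, with 13 called when adjusted over the list alone. Its camera adjusted p was 8.96e-06, with adjusted p = 0.5 with an estimated correlation. In the osteoclast list 3 of 9 measured genes were higher, 0 lower and 6 did not pass, with 4 called when adjusted over the list alone. Against other genes, camera gave 0.00356, with adjusted p = 0.114 with an estimated correlation. Il12b went from 0.95 ± 0.975 to 8.32 ± 3.86 in WT and from 2.28 ± 1.26 to 222 ± 82.4 in KO, a difference of 3.79 ± 0.872 (adjusted p = 0.0111, but 0.219 with edgeR and 0.0598 with a pseudocount of 0.5).

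Several immediate early genes went the other way. Nr4a1 moved from 166 ± 13.2 to 303 ± 66.2 in WT and from 199 ± 31.4 to 75.5 ± 22 in KO (difference -2.26 ± 0.276), and Fos from 1937 ± 49.6 to 4321 ± 1470 and from 2679 ± 259 to 1422 ± 368 (difference -2.05 ± 0.257). Zfp36 (-1.14 ± 0.148), Btg2 (-0.98 ± 0.106) and Nr4a3 (-3.54 ± 0.621) also differed. In the immediate early list 0 of 17 measured genes were higher, 10 lower and 7 did not pass, with 12 called when adjusted over the list alone. As a set its camera adjusted p was 5.2e-08 and adjusted p = 0.0463 with an estimated correlation, the list call that held in this comparison. Without WT IFN-gamma replicate 1, which stood apart from the others of its group, 8 genes were lower (camera adjusted p = 3.99e-08, and 0.0295 with an estimated correlation). With an estimated correlation the call was lost without WT untreated replicate 1 (0.0786), WT untreated replicate 2 (0.0548), WT untreated replicate 3 (0.0619), KO untreated replicate 2 (0.058), KO untreated replicate 3 (0.0638), WT IFN-gamma replicate 2 (0.066), KO IFN-gamma replicate 1 (0.0734) or KO IFN-gamma replicate 2 (0.0728). Il1b rose less in KO (difference -3.44 ± 0.825, adjusted p = 0.0144), and Slc4a11 (-3.81 ± 0.664), H1f2 (-3.15 ± 0.431), Xcr1 (-2.91 ± 0.701), Gja1 (-2.84 ± 0.695), Stat4 (-2.51 ± 0.482) and Fam43a (-2.48 ± 0.569) differed in the same direction. For cholesterol synthesis and uptake 2 of 23 measured genes were higher, 0 lower and 21 did not pass, with 2 called when adjusted over the list alone. The camera adjusted p was 0.0347 and adjusted p = 0.977 with an estimated correlation. The differences of Cxcl9, Nos2 and Irf1 did not pass (adjusted p = 0.62, 0.558 and 0.86, looked up outside the naming rule). In simulated data with equal folds in both genotypes 47 such calls were false, 21 of them with a mean under 50. They made up 25.4% of the simulated calls. That share depends on the simulated number of changed genes (67, 67 and 66 at 1.5-, 2- and 4-fold). It is no estimate of the false share among the 1307 calls here. The Ldha difference of 0.36 ± 0.108 lay near the threshold (adjusted p = 0.0466, and 0.0519 with edgeR, 0.0519 with the libraries compared alone and 0.0718 with no filter on low values). It did not pass without WT untreated replicate 1 (0.111), WT untreated replicate 2 (0.117), KO untreated replicate 1 (0.128), KO untreated replicate 2 (0.11), WT IFN-gamma replicate 1 (0.0718), WT IFN-gamma replicate 3 (0.0887), KO IFN-gamma replicate 1 (0.0589), KO IFN-gamma replicate 2 (0.0692) or KO IFN-gamma replicate 3 (0.108). By limma 1307 genes passed, 615 higher and 692 lower, 418 of them at least 2-fold. With the animals as a replicate block 2073 passed. The count was 760 without WT untreated replicate 2, 839 without WT untreated replicate 3, 849 without KO untreated replicate 2 and 806 without KO untreated replicate 3.

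**Figure D4:**
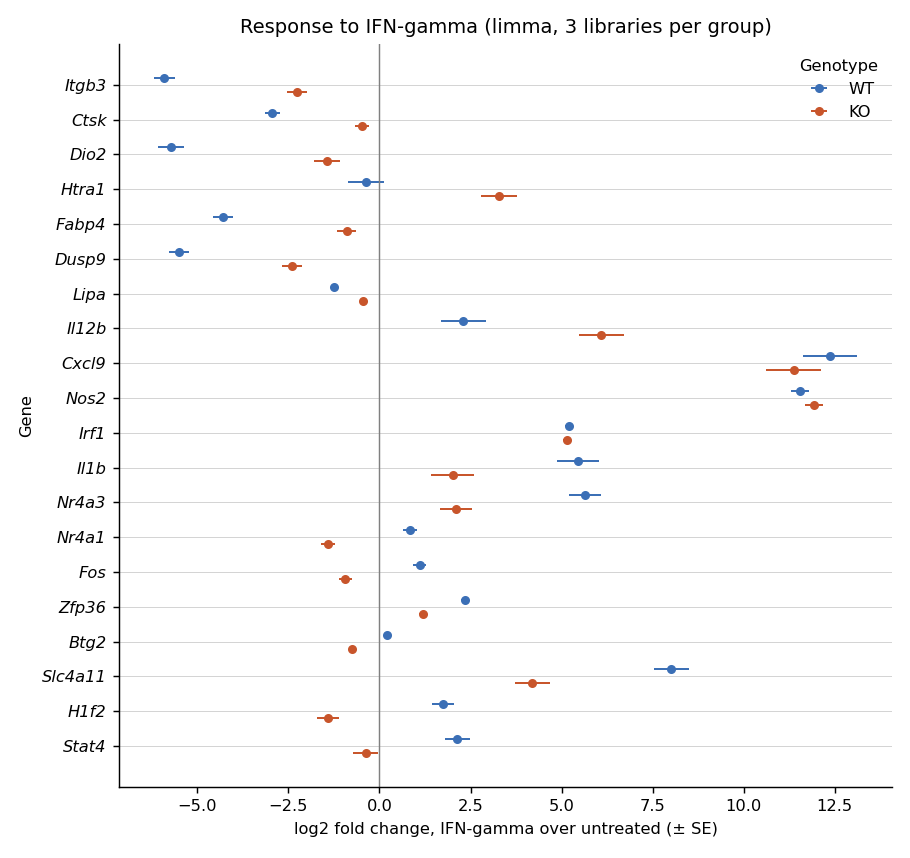
Log2 fold change of IFN-gamma over untreated (points) with its SE (bars) for 20 genes in WT and KO macrophages, 3 libraries per group. The difference between the genotypes was 3.63 for Itgb3, 2.47 for Ctsk, -3.44 for Il1b and -2.26 for Nr4a1.

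The response to IL-4 was compared in the same way, and 1 gene passed by limma, the unnamed model Gm6192 (354 to 77.3 in WT, 327 to 356 in KO, difference 2.31 ± 0.229, adjusted p = 0.000176). At an unadjusted p under 0.05 there were 774 genes. edgeR called 1 and DESeq2 21, and with the animals as a replicate block 12 passed. The count was 2 without WT untreated replicate 1, 2 without WT IL-4 replicate 1 and 3 without WT IL-4 replicate 2. Nos2 rose more in KO by fold (difference 2.19 ± 0.353) but did not pass (adjusted p = 0.0668), whereas it passed with the replicate block (0.0103), with DESeq2 (0.000231), after quantile normalization (0.019), with a pseudocount of 5 (0.0312), with no filter on low values (0.0344) and without WT IL-4 replicate 1 (8.18e-06) or WT IL-4 replicate 2 (0.0455). Pecam1 (-2.31 ± 0.42, adjusted p = 0.13) passed with the replicate block (0.00934), with DESeq2 (1.55e-06) and without WT untreated replicate 1 (0.0137). Apobr (-0.52 ± 0.0929) and Tm6sf1 (-0.58 ± 0.112) passed with DESeq2 only (0.000231 and 0.00232). The immediate early list was shifted down in KO: 0 of 17 measured genes were higher, 0 lower and 17 did not pass, with 2 called when adjusted over the list alone. Camera gave an adjusted p of 0.000856, with adjusted p = 0.464 with an estimated correlation. The glycolysis list was shifted down as well: 0 of 18 measured genes were higher, 0 lower and 18 did not pass, with 0 called when adjusted over the list alone. By camera the adjusted p was 0.00567, with adjusted p = 0.704 with an estimated correlation.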

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

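The counts of the other splits of the animals given here were chosen as tests only after the results were seen, whereas the tests of the difference between responses were planned. Each value below drew attention because the response to the same treatment differed between WT and KO by a test of that difference (limma interaction term, or camera on it). Values are KO minus WT on the log2 scale, and lists carry the camera adjusted p.

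In the response to IFN-gamma 1307 genes differed. Dio2 (4.27), Htra1 (3.65), Itgb3 (3.63), Fabp4 (3.40), Dusp9 (3.08), Olfr111 (3.06), Spsb4 (2.80) and H2-M2 (2.58) stood higher in KO relative to WT, and H2-M2 has close relatives with which it can share reads. Il12b (3.79, but adjusted p = 0.219 with edgeR and 0.0598 with a pseudocount of 0.5) and Nat8l (2.59) did so at low counts. Nat8l had 0 reads in WT with IFN-gamma and 2.08 normalized counts in KO, so the size of its difference depends on the pseudocount, and it did not pass without WT untreated replicate 2 (0.0625), WT untreated replicate 3 (0.0551), KO untreated replicate 1 (0.0642), KO IFN-gamma replicate 1 (0.0647) or KO IFN-gamma replicate 3 (0.0577). Cathepsin K (Ctsk, 2.47), Ocstamp (2.33), Gpnmb (1.24), Lipa (0.80) and Gaa (0.53) came from the lysosome list (8.96e-06) and the osteoclast list (0.00356), and Lss (0.65) and Hsd17b7 (0.73) from cholesterol synthesis and uptake (0.0347). With an estimated correlation these list calls were lost (0.5, 0.114 and 0.977). Lss did not pass without KO untreated replicate 2 (0.052), KO untreated replicate 3 (0.051) or KO IFN-gamma replicate 1 (0.0501). Hsd17b7 did not pass without WT untreated replicate 1 (0.0644), WT untreated replicate 2 (0.0533), WT untreated replicate 3 (0.0675), KO untreated replicate 2 (0.0895), KO untreated replicate 3 (0.084), WT IFN-gamma replicate 1 (0.065), KO IFN-gamma replicate 1 (0.0731) or KO IFN-gamma replicate 2 (0.0668). Ocstamp was at 0 reads in untreated KO and missed the threshold with edgeR (adjusted p = 0.263) and without KO untreated replicate 3 (0.05), WT IFN-gamma replicate 1 (0.0555), KO IFN-gamma replicate 1 (0.0658) or KO IFN-gamma replicate 2 (0.0543). Gpnmb missed it after quantile normalization (0.19). Ldha differed by 0.36 near the threshold (adjusted p = 0.0466). It did not pass with no filter on low values (0.0718), with edgeR (0.0519) or with the libraries compared alone (0.0519). Nor did it pass without each of several libraries in turn (0.0589 to 0.128, listed above).

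Lower in KO relative to WT were Slc4a11 (-3.81), Nr4a3 (-3.54), Il1b (-3.44), Cd226 (-3.18), H1f2 (-3.15), Xcr1 (-2.91), Gja1 (-2.84), Chrm3 (-2.74), Stat4 (-2.51) and Fam43a (-2.48). Cd226 was at 0 reads in untreated WT and passed with neither edgeR (adjusted p = 0.196) nor DESeq2 (0.108), and Chrm3 did not pass without KO untreated replicate 1 (0.0502). Btg2 (-0.98), Nr4a1 (-2.26), Fos (-2.05) and Zfp36 (-1.14) came from the immediate early list (5.2e-08, and 0.0463 with an estimated correlation). With each library left out, a choice made after the results were seen, its adjusted p was 2.43e-08 to 1.84e-07. The estimated correlation lost the call without each of several libraries in turn (0.0548 to 0.0786, listed above). WT IFN-gamma replicate 1 held the highest Il1b of its group (42080 against 14747 and 14350) and the highest H1f2 (10961 against 3835 and 3475), and both genes also passed without it.

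In the response to IL-4 1 gene differed, Gm6192 (2.31). Immediate early genes (0.000856), glycolysis (0.00567), macrophage identity (0.00567), type I interferon response (0.0277) and HIF targets outside glycolysis (0.0354) were shifted down in KO relative to WT, with 0 genes called by limma in each list. These list calls were lost with an estimated correlation (adjusted p = 0.464, 0.704, 0.704, 0.968 and 0.704).

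Among the 10 splits of the 6 animals into 3 and 3, the real one alone reached the count in either response (1 of 10 splits). The highest count of another split was 0 against 1307 for IFN-gamma and 0 against 1 for IL-4, and 10 splits are too few for a share under 0.05. Every other split mixes both genotypes, so a real difference between them widens its spread and lowers its count. Low counts there therefore do not argue against chance. No explanation was tested for single genes of this part.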

How the results depend on the processing

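The stromal covariate, the identity list without Lyz2 and the immediate early list with libraries left out were chosen as tests only after the results were seen, and the other alternatives were planned. Of 10291 alternative values for 623 results of named genes, 9956 kept their direction and side of the threshold, 287 kept direction but missed the threshold, 29 passed it newly and 19 changed sign. Left-out libraries made 207 of the 287, the libraries compared alone 29, edgeR 18 and quantile normalization 10. TMM kept 108 and quantile normalization 98 of the 112 list calls, with 0 turned. No scaling moved the median of all genes by over 0.1. Each scaling sets the libraries to a common level, so a shift of most genes would not show. For values given next, the cause was not tested unless fewer libraries or a stricter threshold explain it. Depth limits genes near 0 reads, for which only bounds or intervals are given, and WT IL-4 replicate 2 with 9.77 M reads most.

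Counts of called genes moved by over 1.5 times as follows. KO against WT in untreated cells (283): DESeq2 608, libraries compared alone 971. KO against WT with IL-4 (941): libraries compared alone 128. Response to IFN-gamma (1307): replicate block 2073. Response to IL-4 (1): pseudocount of 5 3, no filter 2, quantile normalization 2, DESeq2 21, replicate block 12. Animal means (1618): edgeR 869, replicate block 1031. At a log2 change of at least 1 the counts were 115, 883 and 276 for KO against WT (untreated, IFN-gamma, IL-4), 3911 and 3280 for IFN-gamma in WT and KO, 1304 and 1282 for IL-4, 418 and 1 for the responses and 338 for animal means. Leaving out 1 library gave 124 to 209, 2926 to 3574 and 497 to 1009 for KO against WT, 8040 to 8381 and 7072 to 7353 for IFN-gamma, 3238 to 4552 and 3354 to 4431 for IL-4, 760 to 1251 and 1 to 3 for the responses and 743 to 1759 for animal means. The random animal block and the other settings stayed within 1.5 times.

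With an estimated correlation the lists called went from 11 to 1 for KO against WT in untreated cells, 5 to 0 with IFN-gamma and 12 to 2 with IL-4, from 16 to 1 and 15 to 1 for IFN-gamma in WT and KO, 23 to 5 and 21 to 5 for IL-4, 4 to 1 and 5 to 0 for the responses and 10 to 0 for animal means. Fry, which asks another question, called 7 and 13 (KO against WT, untreated and IFN-gamma), 32 and 26 (IFN-gamma) and 0 (response to IL-4). The stromal covariate gave 6 lists with IL-4, and 403, 2763 and 736 genes for KO against WT, of which 200, 2478 and 581 were also called without it. With each library left out the immediate early list had camera adjusted p = 1.78e-06 to 7.73e-06 for KO against WT with IFN-gamma. An estimated correlation gave 0.0875 to 0.205, none passing. For the response to IFN-gamma these were 2.43e-08 to 1.84e-07 and 0.0295 to 0.0786.

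For KO against WT the replicate numbers join different animals. A replicate block on them gave 378, 4153 and 1059 genes and called Arg1 with IFN-gamma (adjusted p = 0.0496) and the pentose phosphate list with IL-4 (0.0476). In the response to IL-4, where the block is the animal, it called the respiratory chain and heat shock lists (0.0422 each), Nos2 (0.0103) and Pecam1 (0.00934). For animal means the matrix list was called (0.0282) and Acaa2 (0.0677), Pcna (0.0541), Aurka (0.0611) and Pdgfrb (0.0674) were lost. The replicate block changed no other list call or call of a named gene.

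Sign changes occurred only in results that had not passed, with ranges over single libraries left out given first. For KO against WT, Nos2 untreated gave -0.038 to 0.23 (turned without KO replicate 1) and Cxcl9 untreated -0.21 to 0.65 (turned without WT replicate 2). With IL-4, Cxcl9 gave -1.36 to 0.63 (turned without WT replicate 1, 0.20, WT replicate 3, 0.29, and KO replicate 1) and 0.058 with the stromal covariate, Arg1 -0.35 to 0.053 (turned without WT replicate 1 and, 0.047, KO replicate 2), and Chil3 -0.54 to 0.19 (turned without KO replicate 2) and 0.054 with the stromal covariate. For IFN-gamma in WT, Arg1 gave -0.41 to 0.58 (turned without WT untreated replicate 1, 0.081, WT untreated replicate 2, 0.035, and WT IFN-gamma replicate 1), 0.032 with a pseudocount of 5, 0.16 after quantile normalization, 0.16 with edgeR and 0.18 with DESeq2. Chil3 gave -0.31 to 0.95 in WT (turned without WT IFN-gamma replicate 3) and -0.20 to 0.97 in KO (turned without KO untreated replicate 1). Ldhb in the response to IL-4 gave -0.24 to 0.042 (turned without WT untreated replicate 3, 0.0041, and KO IL-4 replicate 2).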

Other observations

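Only the tests of gene positions near Ldha and Lyz2 were written before their result was seen; the other tests of this part, the counts over other splits included, were chosen after. Further genes, chosen after their values were seen, passed in all 3 KO against WT comparisons by limma (n = 3 libraries per group). Hmox1, which degrades heme, was higher by 0.73, 0.49, 0.75 (untreated, IFN-gamma, IL-4). The secreted or surface signals Kitl (0.57, 1.61, 1.06), Vegfc (1.81, 2.28, 1.86), Jag1 (0.79, 0.76, 0.90) and Ccl22 (1.41, 2.57, 1.97) were higher, as were Mdm2 (0.57, 0.44, 0.77), which lies within 10 Mb of Lyz2, Aen (0.39, 0.75, 0.53) and Sfn (1.21, 1.57, 0.86). Lower were the neonatal Fc receptor gene Fcgrt (-0.40, -1.41, -0.62), which lies within 10 Mb of Ldha, the phospholipid carrier Pltp (-0.65, -0.64, -0.84), the sterol hydroxylase Cyp27a1 (-0.52, -0.97, -0.83), the selenium carrier Selenop (-0.79, -0.62, -1.18) and the lysosomal protease Lgmn (-0.44, -0.42, -0.49). Highest adjusted p over these values was 0.0385.

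Xist, transcribed from the inactive X chromosome, stood at 11972 to 22656 normalized counts over the 18 libraries. WT IL-4 replicates 2 and 3 were the only libraries that correlated best, after subtraction of group means, with libraries of another replicate number in both other treatments. WT IL-4 replicate 2 had r = 0.088 and 0.061 with WT replicate 3 and 0.037 and 0.049 with WT replicate 2 (untreated, IFN-gamma), and WT IL-4 replicate 3 had 0.12 and 0.11 with WT replicate 2 and 0.0036 and 0.05 with WT replicate 3. The labels were kept. Comparisons of groups do not use the order of replicates within one, but analyses that join libraries by animal code depend on these labels. Among them are the animal means (1618 genes), the replicate block, which in the response to IL-4 called 12 genes with Nos2 and Pecam1 among them, the random animal block, the splits of the animals for the responses and the animal means, and the animal mean stromal scores. How far other codes would move them was not tested.

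Lyz2 fell by over 9 log2 units in KO in each treatment, and 2 explanations were tested. Reads that Lyz2 shares with Lyz1 are argued against, since Lyz1 gained none of what Lyz2 lost (at most -0.011% of it). Fewer macrophages in the KO cultures are argued against as well, since the median change of the 17 other identity genes was no lower than -0.297. An insertion at the Lyz2 locus of the KO animals, such as a recombinase placed there to delete Ldha in macrophages, may explain it. That Lyz2 lay under 1% of the lowest WT library of its treatment in 9 of 9 KO libraries restates the loss and is no test of this. The labels do not state how the KO was made, and insertion and loss of Ldha cannot be told apart because both go with the genotype.

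Stromal and fibroblast markers ranked above other genes in KO by camera (adjusted p = 1.08e-07, 0.0338 and 0.00417 untreated, with IFN-gamma and with IL-4), calls lost with an estimated correlation (0.289, 0.868 and 0.735). Of the 15 markers 0, 3 and 0 passed singly, and together they made up 0.000854 to 0.00877% of reads. Within groups the 15 markers ordered the replicates alike, with a mean Kendall concordance of 0.56. Over 1000 random lists matched on expression the median was 0.0667 and the 95th percentile 0.125, with 0 as high. Stromal cells in differing amounts may give this, as may genes that change together in macrophages. None of the 15 markers belongs to another fixed list (0), and of the most abundant Col1a1 stood at 188 ± 132 in WT and 416 ± 202 in KO with IL-4 and Sparc at 38.3 and 157 untreated. Animal mean scores were 6.04, 6.29 and 4.93 in KO and 4.05, 4.88 and 4.7 in WT, a difference of 1.21 (exact two-sided permutation p = 0.1, the lowest the design allows). More stromal cells and loss of Ldha raising these genes in macrophages cannot be told apart, as both would raise the score. NRF2 targets passed with the marker score as a covariate (adjusted p = 5.17e-34, 1.28e-13 and 6.07e-31).

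Sequence of another strain kept around an altered locus could carry differences of its own. Of the 126 genes called in the same direction in all 3 KO against WT comparisons (Ldha and Lyz2 left out), 2 (Atf5 and Fcgrt) lay within 10 Mb of Ldha, 1.59% against 0.966% of genes tested (one-sided Fisher exact p = 0.344). That so few lay there argues against such sequence, acting on nearby genes, as the source of most shared changes. A test on 2 genes cannot decide for Atf5 and Fcgrt themselves, for which it remains open. Effects of such sequence on distant genes were not tested. Within 10 Mb of Lyz2 lay 3 (Agap2, Glipr1 and Mdm2), 2.38% against 0.56% (one-sided Fisher exact p = 0.0337, adjusted over both tests 0.0674). Flanking sequence acting on genes within this distance of Lyz2 may thus account for at most 3 of the 126, and it remains open for these.

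Calls were recounted for all 10 splits of the libraries (animals for the animal means) into 3 and 3, which are too few for a share under 0.05. In each comparison 1 of the 10 splits, the real one, reached the count. The highest count of another split was 0 for KO against WT untreated (real 283), for IFN-gamma in WT (8922) and KO (7970), for IL-4 in WT (4332) and KO (4318) and for animal means (1618). For KO against WT it was 1 with IFN-gamma (3980) and 547 with IL-4 (941), which points to a structure among the IL-4 libraries beyond genotype.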
